A study of Arabidopsis thaliana with 4 samples.

How the data were processed

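Total RNA of 35S::Dof3.2-GR seedlings was measured on 4 one-colour Affymetrix arrays with biotin-labelled target, per the labels' protocols. Groups were taken from the treatment label, 2 arrays for mock and 2 for 10 µM DEX, and all 4 value columns were matched to samples by name. The deposited values are intensities on a linear scale, made with MAS5 per the submitters' processing notes, with the version and settings not given in the sources used here. MAS5 subtracts a local background, corrects with mismatch probes and scales each array as a whole. The mean after leaving out the lowest and highest 2% of values was 500 on every array, so a change in total RNA per cell cannot be seen. No detection calls were used here, and dim probe sets on this scale are noisy. For arrays, their number limits the precision.

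The table held 22810 probe sets, of which 64 control probe sets were left out of every test. The remaining 22746 were put on the log2 scale without a pseudocount. Probe sets with a mean log2 value under the 40th percentile, a signal of about 111, were left out, which kept 13648 and left out 9098. The array annotation listed 14016 probe sets, 13513 with 1 gene and 503 with several, and 8794 of the table were not listed and are unnamed here. Symbols were updated through gene identifiers in a RefSeq gene table of assembly TAIR10.1, in which 13436 probe sets matched a locus; of the kept ones 7275 were named. Genes without a symbol there carry their locus code, and COG1, CDF5 and other members of the lists then carry the common name written in the list. No genome build is named for the array, so no coordinates are given. A probe set paired with several genes or none was not named.

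DEX was compared with mock in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a group term only and moderated variances that follow the mean, two-sided, with Benjamini-Hochberg adjustment over the kept probe sets at a threshold of 0.05. Intervals are 95% intervals of that fit. The prior had 7.74 degrees of freedom and each test 9.74, of which 2 came from the arrays themselves, so most of the precision was borrowed across probe sets. The median standard error of a log2 change was 0.14. Simulated data of the same size were drawn from the variance prior that the same fit had estimated. On them the fit recovered 93% of 100 probe sets changed 2-fold and 100% of 100 changed 4-fold. It made 10 false calls among 203 (4.93%). The self-test draws normal errors with equal spread in both groups and does not cover shared technical differences between arrays. Its errors follow the model of the fit, so a false share near the threshold was built in and says little about the real arrays. There the median absolute log2 difference was 0.162 between the mock arrays and 0.118 between the DEX arrays. An exploratory fit of the real values was made before this self-test was written, and the test settings had been fixed earlier.

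Gene lists (25, with 586 members) were written from general knowledge before the data were examined, as were the test, the filter and the naming rule. A list with at least 5 kept members was tested with camera at a preset correlation of 0.01, adjusted over those lists, with an estimated correlation and fry beside it; a gene with several probe sets was represented by the brightest. On simulated data with independent probe sets, camera called the 1 list whose members were all shifted by 0.5 on the log2 scale. It called 0 of 24 unchanged lists of 8 members each. Without correlated probe sets, this does not test whether the preset correlation holds for real lists. With an estimated correlation, camera uses only the 2 degrees of freedom that come from the arrays themselves. That form therefore has little power here, and a list that does not pass in it is left undecided. Named in the text are the 12 single-gene probe sets in each direction with the largest log2 change among those past the threshold with fully separated groups, up to 4 members of each list with the lowest p, and Dof3.2, for which 0 probe sets were annotated. The unnamed probe sets were chosen for print after their values were seen, 2 in each direction. A further 4 gene families were defined after the called genes were seen, and their tests appear only in the closing section.

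Alternatives fixed before the data were examined were quantile normalization, median centring, no filter, a filter at the 60th percentile, a pseudocount of 22.1, variances without a trend or with robust estimation, the replicate number as a block, probe sets of 1 gene only, each array left out, another summary of several probe sets of a gene, and 1.5-fold and 3-fold limits for the count over pairs. A filter at the 20th percentile and a variance model fitted on all probe sets were chosen after seeing the data.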

Results

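Transcript levels were measured in Arabidopsis thaliana seedlings that carry 35S::Dof3.2-GR. In such a line a constitutive viral promoter drives a fusion of Dof3.2, a plant transcription factor of the Dof zinc finger family, to the hormone-binding domain of the glucocorticoid receptor. A fusion of this kind is held outside the nucleus until a synthetic glucocorticoid such as dexamethasone (DEX) is given. Seedlings spent 4 days on agar with 1% sucrose and 50 µg/ml kanamycin at 22 °C and then 4 days in shaken liquid medium. They then received 10 µM DEX or a mock treatment for 3 h. The data comprised 4 one-colour Affymetrix arrays, 2 from mock-treated and 2 from DEX-treated seedlings. The design asks which transcripts change in level within 3 h of DEX in this line.

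Each array gave 22810 MAS5 signals. The median signal was 193.3 and 192.8 on the mock arrays and 190.6 and 193 on the DEX arrays. Over the 13648 probe sets kept for testing, the log2 signals of the DEX arrays correlated at r = 0.992 with each other across probe sets, and those of the mock arrays at r = 0.985. The mock and DEX arrays correlated at r = 0.982 to 0.986 across groups. The array carries an older and a newer set of control probe sets for the 3′ to 5′ signal ratio, a sign of RNA integrity. In the older set, GAPDH had ratios of 1.62 and 1.53 on mock replicate 1 and 2 and 1.33 and 1.6 on DEX replicate 1 and 2, and ubiquitin 2.8 and 3.34 on the mock and 3.46 and 3.18 on the DEX arrays. Actin in that set had 10.5 and 18.5 on the mock arrays and 18.6 and 17.3 on the DEX arrays, with mock replicate 1 apart from the rest. In the newer set, GAPDH had 1.16 and 1.11 on the mock arrays and 1.18 and 0.952 on the DEX arrays, and actin 3.15 and 3.34 on the mock arrays and 3.17 and 2.53 on the DEX arrays. Ubiquitin in the newer set had 1.58 and 1.48 on the mock arrays and 1.37 on both DEX arrays, the 1 ratio of the 6 whose groups did not overlap. The labels do not say whether replicates came from separate cultures, so every p-value measures only the spread between these arrays, which may be technical. No probe set was paired with the locus of Dof3.2 in the annotation used, so the transcript of the fusion was not analysed here. Its level would describe the line and would not check the treatment labels.

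The largest rises among named genes after DEX were those of AT4G36430, which encodes a class III peroxidase (secreted haem enzymes that oxidise phenolics in the cell wall), and AT4G11210, which encodes a dirigent protein (a family that steers the coupling of phenolic radicals). The signal of AT4G36430 went from 370.2 ± 5.56 in mock to 2109 ± 123 in DEX seedlings (SD, n = 2 each), a 5.69-fold rise. That of AT4G11210 went from 117.4 ± 12.1 to 645.6 ± 2.33 (SD, n = 2 each), a 5.51-fold rise. CDF4, itself a Dof transcription factor gene (AT2G34140), rose 2.93-fold. The largest named falls were smaller than these rises, and the genes that fell included 4 further class III peroxidase genes, a grouping made after the calls were seen: AT4G26010, AT3G03670, AT3G01190 and AT5G64100 fell 2.41-fold, 2.14-fold, 2.1-fold and 2.03-fold. In all, 40 probe sets rose and 40 fell among the 13648 tested (limma with Benjamini-Hochberg adjustment, two-sided, threshold 0.05).

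Of the 80 probe sets, 19 rose and 26 fell by at least 2-fold. The median change was 1.99-fold among those that rose and 2.07-fold among those that fell, and the range over all 80 was 1.53-fold to 8.57-fold. In each of the 80, both DEX values lay beyond both mock values, which 39.3% of all tested probe sets showed and chance alone gives in 33.3%. Without any model, 21 probe sets differed by at least 2-fold in all 4 DEX against mock pairs, 13 of them higher and 8 lower in DEX. The other 2 ways to divide the arrays into 2 and 2 gave 0 and 1 such probe sets, and 0 limma calls each, with 597 and 259 probe sets at an unadjusted p under 0.05 against 1263 in the real division. That contrast rested on the filter: without it the real division gave 471 and the other 2 gave 431 and 426, a comparison chosen after seeing the data. An exact permutation test of a single gene cannot go below a two-sided p of 1 in 3 with 2 arrays against 2. The limma count was 25 without the filter on dim probe sets, 27 and 25 without DEX replicate 1 and 2, and 496 and 260 without mock replicate 1 and 2; the count of at least 2-fold calls was 25 without either DEX array and 77 without mock replicate 1, and the count over pairs, of which fewer then remained, was 36 and 32 without DEX replicate 1 and 2 and 58 and 34 without mock replicate 1 and 2. A fit without 1 array takes its spread only from the group that keeps 2 arrays. No DEX-treated seedlings without the fusion were analysed here, so an effect of DEX itself is included in every value.

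**Figure D1:**
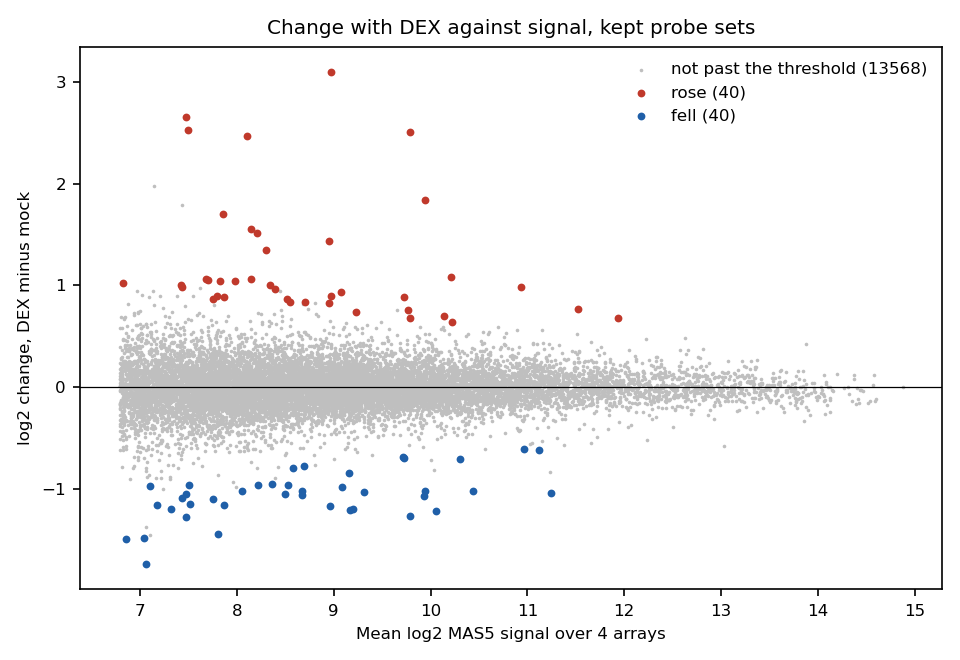
Each point is 1 of the 13648 tested probe sets, with its mean log2 MAS5 signal over the 4 arrays on the x axis and its log2 change (DEX minus mock) on the y axis. The 40 probe sets that rose are red and reach higher values than the 40 that fell, in blue.

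Among the 80 probe sets, 38 were paired with a single gene, 18 that rose and 20 that fell. The named risers beyond those above covered several functions. AT5G60800, which encodes a heavy-metal-associated domain protein, rose 2.86-fold. PDF1.2b, which encodes a secreted antifungal defensin, rose 2.12-fold, from 819.2 ± 120 to 1724 ± 61.1 (SD, n = 2 each). Its probe set, marked x_at, is of a kind that can share signal with near-identical defensin genes, so the rise cannot be assigned to this copy alone. AT5G12420, which encodes a wax ester synthase-like acyltransferase, rose by a log2 change of 1.00 ± 0.15 (SE). The protein kinase gene AT5G35580 and AT5G09800 rose 2-fold and 2.03-fold. AT4G33380 and AT3G16330 rose 3.57-fold and 3.25-fold. AT3G02910 and AT1G44760 rose 1.98-fold and 1.86-fold. The adjusted p of limma for these 12 risers ran from 1.48e-05 for AT4G36430 to 0.0498 for AT5G09800.

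The largest fitted fall among named genes was that of AT1G26380, which encodes a berberine bridge enzyme-like oxidoreductase with a role in indolic defence compounds. Its signal went from 197.2 ± 42.4 to 69.22 ± 4.2 (SD, n = 2 each), a 2.82-fold fall. AT5G04960, which encodes a pectin methylesterase, an enzyme that modifies cell wall pectin, fell 2.43-fold. UGT72E2, which encodes a glucosyltransferase of monolignols and related phenolics, fell 2.05-fold from 911.6 ± 22.1 to 447.8 ± 68.1 (SD, n = 2 each). AT4G15390, which encodes an acyltransferase of the BAHD family, fell 2.06-fold, with mock signals of 2925 and 4172 and DEX signals of 1681 and 1707. AT4G30320, which encodes a secreted protein related to PR-1, fell 2.22-fold, and AT3G07600, which encodes a heavy-metal-associated domain protein, fell 2.21-fold. AT5G40590 and AT5G60520 fell 2.29-fold and 2.07-fold. The adjusted p of limma for the 12 named genes that fell ran from 0.00134 for AT4G26010 to 0.0425 for AT5G40590. In AT1G26380, AT5G40590 and AT4G30320 the DEX mean, and in AT5G09800 the mock mean, lay under the filter level of about 111, where no detection call was used here, so the size of these folds is uncertain. Of the 24 named genes, 10 passed the threshold in every alternative setting that tested them: AT4G36430, AT4G11210, AT4G33380, AT3G16330, CDF4, AT5G60800, PDF1.2b, AT3G02910, AT4G26010 and AT5G64100. Without DEX replicate 1 and 2, 8 and 13 of the 24 did not pass, and without the filter 12 did not; all kept their direction.

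**Figure D2:**
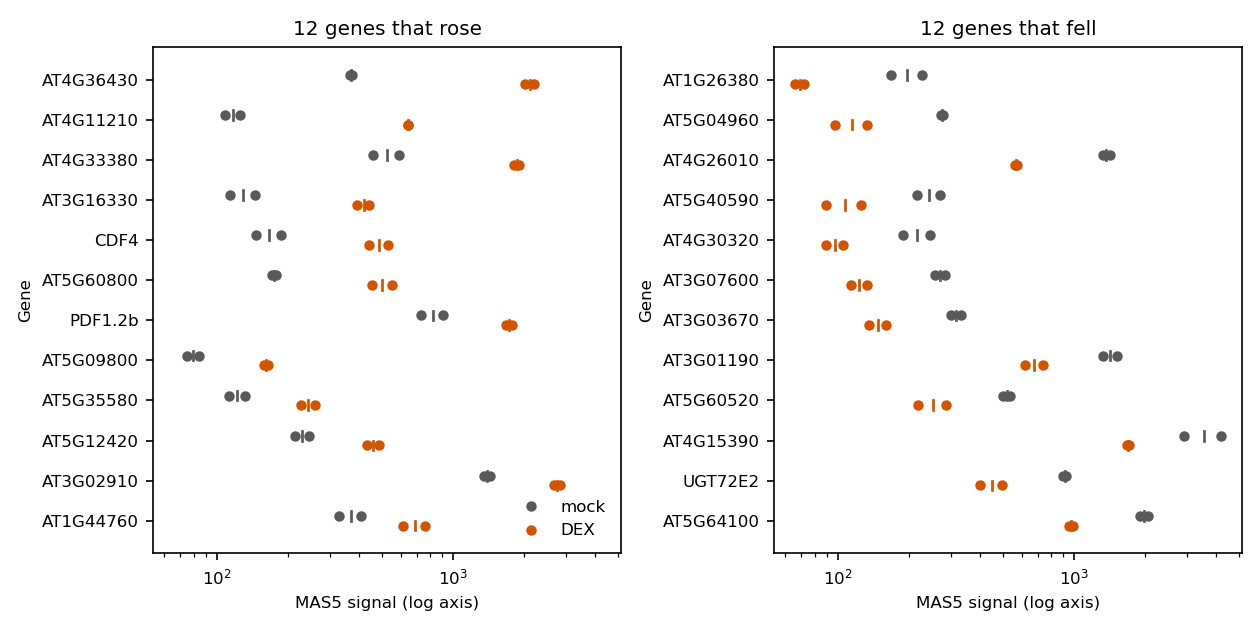
Each row is 1 named gene, with the MAS5 signal of each array on a log axis (points; 2 mock arrays in grey, 2 DEX arrays in orange) and the group mean as a short vertical line. The left panel holds the 12 genes that rose, with AT4G36430 at 370.2 in mock and 2109 in DEX, and the right panel the 12 that fell. In every row the groups do not overlap, which the rule for naming genes required.

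The other 42 probe sets past the threshold were not paired with a single gene in the annotation used. They included the probe set with the largest change of the 80, whose signal went from 178.4 ± 66.5 to 1475 ± 34.3 (SD, n = 2 each), an 8.57-fold rise. The next largest rise among them was 6.31-fold. The 2 largest falls among them were 3.34-fold and 2.79-fold, and neither passed without DEX replicate 1 (adjusted p = 0.0549 and 0.0575, limma), without the filter (0.109 and 0.0834) or with a variance model on all probe sets (0.07 and 0.0521). The lower group means behind these 2 falls and the 6.31-fold rise, 73.72, 79.33 and 75.13, also lay under the filter level of about 111, so these sizes are uncertain too.

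Gene lists for the Dof family, hormones, vascular tissue, metabolism, stress, the clock, the cell cycle and tissue markers asked whether groups of genes moved together. Only 74 of the 586 list members had a probe set of their own in the annotation and 50 were bright enough to test, so 3 of the 25 lists could be tested as sets. Of all 22810 probe sets, 13436 matched a locus, a larger share, though one of probe sets and not of genes. The 4 families of the closing section, chosen later, had 55 of 74, 15 of 25, 44 of 66 and 22 of 27 members annotated. The planned lists were thus covered less well than those families, and their tested members may not represent them. The Dof family had a median log2 change of 0.36, past the threshold in camera with a preset correlation (adjusted p = 0.000983 over 3 lists) but not with an estimated correlation (adjusted p = 0.211) or in the directional fry test (adjusted p = 0.155). The estimated correlation was 0.013, near the preset 0.01, so a stronger correlation among the members does not explain the lost call. With an estimated correlation camera takes its degrees of freedom from the few arrays alone, so it has little power here and cannot decide. Of its 6 tested members, 1 rose, CDF4, from 166.5 ± 28.7 to 485.5 ± 62.9 (SD, n = 2 each; adjusted p = 0.0043, limma), and 5 did not pass. Adjusted over the list alone, 3 rose, CDF4, COG1 and CDF5. COG1 (AT1G29160) had a log2 change of 0.72 ± 0.14 (SE) and CDF5 (AT1G69570) one of 0.65 ± 0.19, with adjusted p over all probe sets of 0.0639 and 0.272 in limma. Without mock replicate 1, COG1 and CDF5 had log2 changes of 0.74 and 0.93. Without mock replicate 2, COG1 had one of 0.70, CDF5 stood at 0.38 and the list's median at 0.23. These 3 genes encode Dof factors of the group that includes the CYCLING DOF FACTORS, known for daily rhythms of expression. DOF4.6 had a log2 change of -0.07 ± 0.15 (SE), and the remaining tested members had changes of 0.06 and -0.04. The list's median of 0.36 thus lay apart from every member and does not describe a shift of the whole family. The set call ended without the filter on dim probe sets and with a looser one, where the list's median was -0.02 and -0.04 while the direction of the test stayed upward (adjusted p = 0.116 and 0.37, camera).

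Among the expansins and xyloglucan endotransglucosylase/hydrolases (XTHs), which loosen or remodel cell walls, 1 of 8 tested members fell and 7 did not pass, over all probe sets and adjusted over the list alone. XTH18 fell 1.74-fold from 504.2 ± 13.1 to 290.5 ± 21.8 (SD, n = 2 each; adjusted p = 0.0361, limma). Without DEX replicate 1 and 2 the adjusted p of XTH18 was 0.128 and 0.356, and without the filter 0.0845. EXPA18, a root hair expansin gene, had a log2 change of -0.43 ± 0.15 (SE), EXPA9 one of 0.22 ± 0.13 and EXPA15 one of 0.16 ± 0.11, none past the threshold. Without mock replicate 1 and 2 the change of EXPA18 was -0.571 and -0.291. The list did not move in one direction as a set (median log2 change -0.02, mean -0.10, adjusted p = 0.383 in camera and 0.586 with an estimated correlation). None of the 5 tested photosynthesis genes, markers of green tissue, passed in limma, whether adjusted over all probe sets or adjusted over the list alone, and 0 had an unadjusted p under 0.05. PORB had a log2 change of -0.23 ± 0.11 (SE), RCA one of -0.16 ± 0.12, LHCB4.2 one of -0.08 ± 0.11 and PRK one of 0.09 ± 0.13. The list's median was -0.08 (adjusted p = 0.349 in camera and 0.586 with an estimated correlation). Without DEX replicate 1 and 2 the median of the photosynthesis list was -0.15 and 0.01. The estimated correlation was 0.37 for this list and 0.14 for the expansins and XTHs, above the preset of 0.01. For these lists, camera at the preset can therefore overstate a shift.

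**Figure D3:**
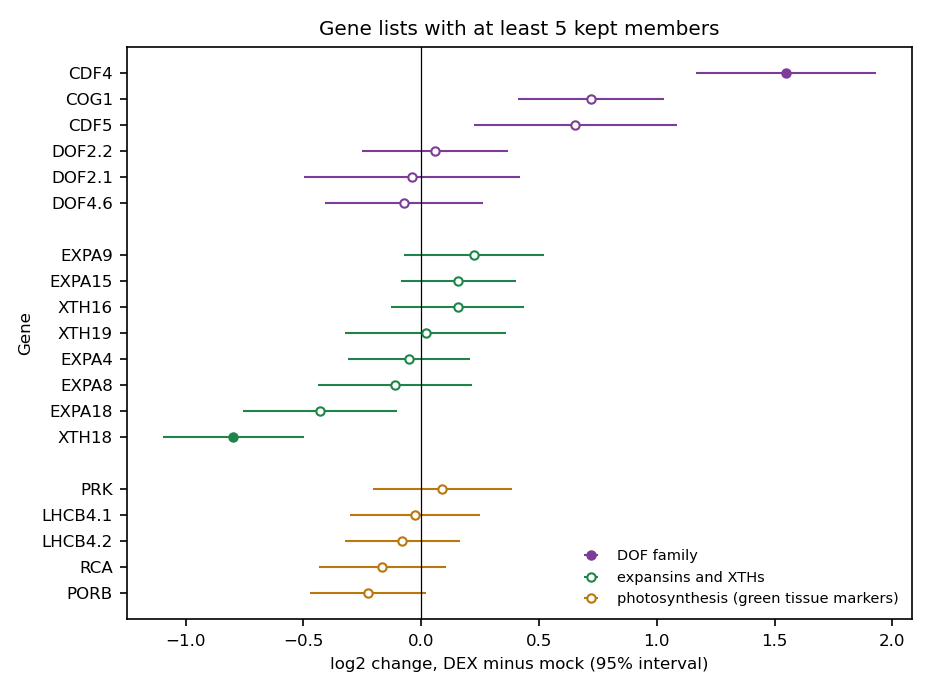
Points are log2 changes (DEX minus mock) of the tested members of the Dof family (purple), the expansins and XTHs (green) and the photosynthesis genes (ochre), with 95% intervals from limma; filled points passed the threshold over all probe sets. CDF4 lies at 1.55 and XTH18 at -0.80, and the 5 photosynthesis genes lie between -0.23 and 0.09.

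The other 22 lists had fewer than 5 tested members and were not tested as sets. None of their 31 tested members passed the threshold over all probe sets in limma, and 8 had an unadjusted p under 0.05. RR16, a cytokinin-inducible response regulator gene, had a log2 change of 0.81 ± 0.18 (SE; adjusted p = 0.107). PDF1.2 of the jasmonate list had one of 0.75 ± 0.17 (adjusted p = 0.115), and BCAT4 of the glucosinolate list one of 0.48 ± 0.11 (adjusted p = 0.12). Without mock replicate 1, RR16, PDF1.2 and BCAT4 had log2 changes of 0.742, 0.862 and 0.589. Without mock replicate 2, RR16 and PDF1.2 had changes of 0.875 and 0.635. In the gibberellin list, the receptor gene GID1B had a log2 change of 0.49 ± 0.15, SLY1 one of 0.33 ± 0.11 and GID1A one of 0.13 ± 0.14 (SE), and GID1B and SLY1 passed when adjusted over the list alone. WRKY53 of the salicylate and immune list stood at -0.51 ± 0.17, GI of the clock list at -0.33 ± 0.14 and STZ of the touch and wounding list at -0.31 ± 0.22 (SE). In the auxin list, GH3.3 stood at -0.35 ± 0.15, HAT2 at 0.22 ± 0.14 and WES1 at -0.22 ± 0.15 (SE). Adjusted over the list alone, BCAT4 passed, while no auxin, touch, vascular, cell cycle or tissue marker gene did. RR16, PDF1.2, WRKY53 and GI were each the single tested member of their list, where that adjustment changes nothing. Their unadjusted p in limma was 0.0011, 0.00122, 0.0131 and 0.0452.

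The root markers PYK10, an abundant root β-glucosidase gene, and EXPA7, a root hair expansin gene, had log2 changes of 0.04 ± 0.10 and -0.22 ± 0.20 (SE). The stomatal lineage genes FMA and SPCH stood at -0.14 ± 0.21 and -0.06 ± 0.18. The vascular genes PHV, LHW, MOL1 and SWEET11 stood at -0.12 ± 0.13, -0.11 ± 0.17, 0.13 ± 0.19 and -0.17 ± 0.10 (SE). The reference genes TIP41L, PEX4 and SAND stood at 0.12 ± 0.12, -0.04 ± 0.11 and -0.01 ± 0.12. The single tested members of 5 further lists, COR15A for abscisic acid, EIN3 for ethylene, LDH for hypoxia, HCT for phenylpropanoids and cICDH for nitrogen assimilation, had log2 changes of 0.25, 0.03, -0.03, 0.05 and 0.09. The cell cycle genes PRL and SIM stood at 0.16 and 0.12, and UGT74B1, the other glucosinolate gene, at 0.17. The brassinosteroid, heat shock and seed and embryo lists had no member that could be tested. The median SE of a log2 change was 0.14, and the smallest change past the threshold was 1.53-fold.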

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

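The values below come from probe sets left out of the comparison as dim, and this look at them was chosen after the other results were seen. In a limma fit of all 22746 probe sets, 2 of the 9098 dim ones passed the threshold. An unnamed probe set had a mean signal of 45.14 in mock and 251 in DEX seedlings (mock arrays 46.82 and 43.47, DEX arrays 249.5 and 252.5; adjusted p = 0.0115, limma). AT1G09470 had a mean signal of 130.1 in mock and 15.1 in DEX seedlings (mock arrays 133.1 and 127, DEX arrays 18.29 and 11.9; adjusted p = 0.0392, limma). The lower group mean of each lies under the filter level of about 111, and no detection call was used here, so the size of the difference is uncertain. By levels alone, 4 dim probe sets had both DEX arrays at or above the filter level and at least 2-fold over both mock arrays, and 5 had the reverse. The other 2 ways to divide the arrays gave 0 and 0. Among the 9, AT1G11170 went from 45.25 to 119.9, while AT5G14650 went from 147.4 to 18.31 and AT2G02680 from 168.6 to 70.48, with adjusted p of 0.21, 0.0886 and 0.132 in limma. No explanation was tested for them.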

How the results depend on the processing

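A filter at the 20th percentile and a variance model on all probe sets were chosen after seeing the data. The 80 calls became 74 to 87 under quantile normalization, median centring, a pseudocount and robust variances, and 60 without a trend. Without the filter on dim probe sets they became 25 (23 shared), with 23 at least 2-fold, 0 lists called, a Dof median of -0.021 and 471 probe sets over pairs. A variance model on all probe sets alone gave 39 and 24, so part of that drop in calls lies in the variance estimate. The rest lies in adjusting over 22746 instead of 13648 probe sets, since these 2 fits share the variance model. The 60th percentile gave 43 and 19, with 0 lists called and under 5 Dof members left; it did not test 33 of the 80. Probe sets of 1 gene gave 39 and 21, with 42 of the 80 not tested. The 20th percentile gave 93 calls, 0 lists and a Dof median of -0.037; the cause was not tested. An estimated correlation and the directional fry test called 0 lists, with the Dof median at 0.356. The fry test for changes in either direction passed for the Dof family (adjusted p = 0.015) and for the expansins and XTHs (adjusted p = 0.0182). It did not pass for the photosynthesis genes (adjusted p = 0.597). Limits of 1.5-fold and 3-fold gave 105 and 6 over pairs, by construction. Leaving out 1 array, where the lone array is assumed to vary like the other group, gave 25 to 496 calls, 25 to 77 at least 2-fold, 1 to 2 lists, and 32 to 58 over pairs. With the replicate block there were 185 calls, all 80 among them; same-numbered arrays deviated together at r = 0.109 across probe sets, and the labels name no shared day. Under the block COG1, RR16, PDF1.2 and BCAT4 also passed (adjusted p = 0.0213, 0.0244, 0.0248 and 0.0306, limma), and no list call changed. Of 348 values of the 24 named genes, 295 kept their side of the threshold, 53 lost it and 0 reversed. Signal near the background limits what dim probe sets can show.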

Other observations

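The 4 gene families, their set tests, and the tests of root tissue, shared signal, hour of harvest and other divisions of the arrays were chosen after the called genes had been seen. Each family holds called genes, so an excess of calls was favoured by the choice. Neither the family counts nor the p-values of the family tests, here and in the next paragraph, are independent evidence. The limma values of single genes come from the planned fit. Class III peroxidase genes went both ways: of 33 tested members, AT4G36430 rose, AT4G26010, AT5G64100, AT3G01190 and AT3G03670 fell, and 28 did not pass (5 rose and 11 fell adjusted over the list alone). These 5 calls exceed the share among all named probe sets, 38 of 7275 (Fisher's exact test, adjusted p = 2.53e-06 over 4 families). The family's median log2 change was -0.27, with 22 of 33 members below 0; camera gave an adjusted p of 0.00012 at the preset correlation and 0.114 with an estimated correlation, and fry one of 0.0965. Among members that did not pass, AT5G15180 had a log2 change of -1.18 ± 0.22 (SE; adjusted p = 0.0522, limma). Median centring gave 6 that fell, quantile normalization 4, and no scaling changed the sign of the family's median. That median was -0.11 without mock replicate 2 and -0.09 without the filter, where 31 of 55 members lay below 0 and 3 fell. The number that fell was 3 without either DEX array, and 10 and 9 without mock replicate 1 and 2, while 4 and 1 rose.

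Of 10 tested dirigent genes, AT4G11210 and AT3G13650 rose and 9 lay above 0 (median log2 change 0.12; Fisher's exact test, adjusted p = 0.00232; camera, adjusted p = 5.28e-05 at the preset and 0.0949 with an estimated correlation; fry, adjusted p = 0.00943). Without mock replicate 1 the median was 0.21 with 3 that rose, and without either mock array 3 lay below 0. AT3G13650 went from 2256 ± 221 to 3830 ± 12.7 (SD, n = 2 each), and 1 dirigent gene rose without either DEX array and without the filter. Of 12 pectin methylesterase genes, AT5G04960 fell and 10 lay below 0 (median -0.22; Fisher's exact test, adjusted p = 0.061; camera, adjusted p = 5.28e-05 at the preset and 0.0949 with an estimated correlation; fry, adjusted p = 0.0284). None of them passed in limma without DEX replicate 2 or without the filter, where AT5G04960 had an adjusted p of 0.13 and 0.0886. Of 9 berberine bridge enzyme-like genes, AT1G26380 fell (median -0.03; Fisher's exact test, adjusted p = 0.061; camera, adjusted p = 0.207 at the preset and 0.363 with an estimated correlation; fry, adjusted p = 0.171), and the median was 0.01 without DEX replicate 1; AT1G26380 did not pass without DEX replicate 2 or without the filter (adjusted p = 0.0738 and 0.0925, limma). Among other genes past the threshold, all outside the naming rule and chosen after their values were seen, AT3G13610, which encodes the hydroxylase F6'H1 of coumarin synthesis, fell from 2744 ± 39.2 to 1799 ± 192, and UGT71C1, a glucosyltransferase gene, from 516.5 ± 14.3 to 265.8 ± 22.9 (SD, n = 2 each).

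The falls of the 4 peroxidase genes might come from less root tissue in the DEX samples, since many class III peroxidases are root genes. Against a loss large enough for the whole of those falls, the 2 root markers fixed beforehand had a median log2 change of -0.092. The 95% intervals of PYK10 and EXPA7 reached down to -0.20 and -0.67, above the median of -1.085 of the 4 genes. A smaller loss stays open, since the 4 genes were selected for having fallen. The whole family's median was -0.274, near EXPA7 at -0.221 but below the interval of PYK10. The root median ran from -0.21 without mock replicate 1 to 0.03 without mock replicate 2, and with any 1 array left out both intervals stayed above the median of the 4 genes. With only 2 markers, and EXPA18 of root hairs at -0.43, a loss of a particular root cell type stays open, as do an effect of the fusion and one of DEX itself, both untested. Signal shared between related transcripts also stays open: none of the 5 called probe sets carries a suffix for shared probes (0 of 5), yet the changes of the 4 genes spanned 0.249, within the 0.309 that 2 standard errors of the difference allow.

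CDF4 rose, and COG1 and CDF5 lay above mock, and such Dof genes follow the time of day. A candidate explanation is a different hour of harvest, which would shift clock genes according to their phases, not all in one direction. GI, the 1 clock gene of 24 that could be tested, had a log2 change of -0.327 (limma, adjusted p = 0.526 over all probe sets, unadjusted p = 0.0452). With 1 such gene, the hour cannot be told apart from an effect of the treatment on these genes.

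For the 80 probe sets past the threshold, 1 of the 3 ways to divide the 4 arrays into 2 and 2, the real one, gave as many, and the highest of the others gave 0 limma calls (597 and 259 at an unadjusted p under 0.05). With 3 divisions, no share under 0.05 can be reached.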
